A study of Bacillus subtilis with 6 samples.

How the data were processed

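Total RNA of Bacillus subtilis TI465 was measured after high hydrostatic pressure. Cells grown for 6 h were held at 250 MPa and 25 °C for 10 min, with pressure changed at 200 MPa per min, and then incubated at 37 °C in L medium without NaCl. There were 3 groups, recovery for 0 h, 2 h and 4 h, with 2 biological replicates each per the labels. RNA was turned into biotin-labelled cDNA with an Affymetrix labelling reagent and hybridised to arrays.

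The values are a score deposited by the authors, 1 table of 5033 features on 6 arrays. R 2.7.2 was used upstream, per the submitters' processing notes. The background correction, normalization and summarization of probes and the log base are not given in the sources used here. The deposited scores had array medians that differed by at most 0.0021, under the limit of 0.2 set for using values as deposited, so no further normalization was applied. That limit had been set for log2 values, and the median range of a gene over the 6 arrays was only 0.00043 score units. Passing it therefore says little about whether the arrays share a scale. The design had assumed log2 values. As the table holds a score, the alternative with a minimum fold that had been chosen beforehand became a minimum difference of 1 score unit, and differences are in score units. The scores barely vary between arrays for most features and vary widely for a few. Among genes of middling score the 95th percentile of the residual SD was 1274 times the 5th, so ranking by a test statistic favours genes with tiny spreads and tiny differences. For arrays, the number of arrays limits the precision.

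Features were named by the platform's annotation table alone. It gives 1 symbol for 2988 features, several for 0 and none for 2045. After 42 control features were left out, 4991 features remained, among them 606 intergenic ones. Features sharing a symbol were averaged (63 genes, of which 13, 12 and 11 had features that differed in sign in the 3 comparisons), which left 4806 genes and unnamed features. Unnamed features are given by their identifier. No gene positions were used.

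Each comparison (2 h against 0 h, 4 h against 2 h, 4 h against 0 h) was tested with limma 3.58.1 in R 4.3.3, on all 6 arrays in 1 fit with 3 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all genes and a limit of 0.05. The empirical Bayes prior had 0.398 degrees of freedom, so the spread of each gene rests almost on its own arrays. Of 47 gene lists, 40 had at least 3 measured members and were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The other 7 were not analysed here. Members were counted as higher or lower when both arrays of 1 time lay beyond both arrays of the other, and were also tested with the p adjusted over the list alone. camera on ranks called 14, 17 and 27 lists in the 3 comparisons, fry called 0, 1 and 5, and camera with an estimated correlation called 0 in each, against 16, 14 and 29. fry tests whether a list moves on balance in 1 direction and does not compare it with other genes.

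The lists, tests, alternatives, 13 genes to report and the naming rule were chosen before the data were examined. The rule names the 6 highest and 6 lowest differences among called genes, and where fewer than 10 genes pass, the 10 of smallest p, given as values. Fewer than 10 passed in each comparison. The genes of largest difference whose groups did not overlap, and up to 3 examples for each called list, were chosen after their values were seen, as were unnamed features. Of the 13 genes, 2, hpf and fusA, had no feature with that symbol and were not analysed under it. Older names of these genes were not looked up among the identifiers of unnamed features.

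Alternatives were quantile normalization, median centring, centring on genes outside the translation lists, leaving out the dimmest 25% of genes, a floor at the 5th percentile, a replicate block, empirical Bayes with trend and robust settings, only the 2 times compared, a stricter adjusted p of 0.01, the minimum difference, and each array left out in turn. Replicate numbers were not taken to pair samples. Without 1 array, a time with a lone array is assumed to vary like the others. The time course was compared with 10000 simulated unchanged genes.

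The tests were tested on simulated data built on the 4806 genes. With 200 genes shifted in each of 20 simulations, limma recovered 16.5% at a shift of 5 residual SDs, 57.6% at 10, 91% at 20 and 96.4% at 40, with 4.73% false calls. camera called the ribosomal protein list, shifted by 2 residual SDs at 2 h, in 20 of 20 simulations. At 4 h against 0 h, with nothing changed, it called 0.05 lists per simulation. The simulated genes varied independently, while the measured ribosomal protein genes had an estimated correlation of 0.817. These rates therefore need not hold for lists whose genes move together. Other splits of the real arrays called 1 to 15 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.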

Results

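Cells of Bacillus subtilis strain TI465, which carries trpC2 and a kanamycin resistance insertion in spoIIAC (sigF, the gene of the forespore sigma factor), were pressed at 250 MPa for 10 min and then allowed to recover. RNA abundance was measured on 6 arrays, 2 biological replicates for each of 3 recovery times. The samples came directly after pressure (0 h), from the growth arrest that followed (2 h) and from re-growing cells (4 h). An untreated culture was not analysed here, so each comparison is between recovery times. Array medians lay between 5.789 and 5.791 score units, and scores ran from 4.97 to 11.2. The score is the deposited expression value, whose log base is not given in the sources used here, so differences are given in score units and never as folds.

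Scores differed little between arrays. The range of a gene over the 6 arrays had a median of 0.00043 score units among 4806 genes and unnamed features, and 85.3% of the ranges were under 0.01. A range over 0.1 was seen for 180 of them, over 0.5 for 31 and over 1 for 4. Across genes, Pearson's r between replicates of one time was 0.9994 at 0 h, 0.9992 at 2 h and 0.9983 at 4 h, where genes are not independent replicates. The root mean square difference between replicates was 0.0216 at 0 h, 0.0248 at 2 h and 0.0354 at 4 h. The array of 4 h replicate 2 lay 0.0300 from 2 h replicate 1 and 0.0347 from 2 h replicate 2, nearer to both than to its own replicate. By the median absolute difference as a percent of a gene's range it lay nearest its own replicate, at 27.0%, against 33.6% from 2 h replicate 1 and 45.15% from 2 h replicate 2. By that measure the other times mixed: 0 h replicate 2 and 2 h replicate 2 were the closest of all pairs, at 20.1%, against 36.1% between the 0 h replicates and 44.9% between the 2 h replicates, and 2 h replicate 1 lay nearer 4 h replicate 2 than its own replicate.

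**Figure D1:**
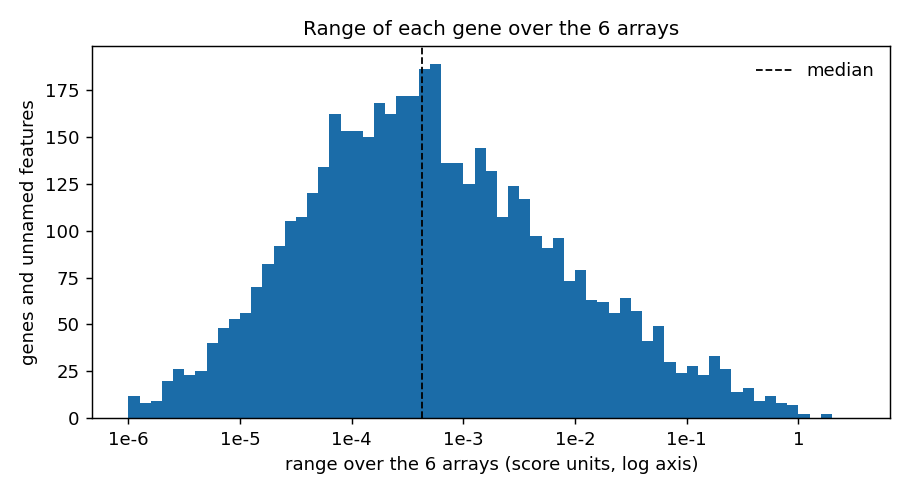
Number of genes and unnamed features (vertical axis) by their range over the 6 arrays (horizontal axis, score units, log scale), with the median as a dashed line. The median is 0.00043, and 180 of the 4806 have a range over 0.1.

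At 2 h, during growth arrest, genes for ribosomal proteins, the GroE chaperonin, cold shock proteins and ATP synthase were higher than directly after pressure. Genes for flagella and chemotaxis, the SigB general stress regulon, the respiratory chain and branched-chain amino acid synthesis were lower. These calls are of lists, rest on a preset correlation between genes, and did not hold with an estimated one. The comparison of 2 h with 0 h asks how growth-arrested cells differed from cells just released from pressure. HrcA represses the groES-groEL and dnaK operons, whose products fold other proteins, and CtsR represses clp genes, whose products unfold and degrade proteins. SigB is the sigma factor of the general stress response, and hag encodes flagellin, the protein of the flagellar filament.

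Of 48 ribosomal protein genes measured, 39 were higher on both 2 h arrays than on both 0 h arrays and 2 were lower. Their mean difference was 0.107 ± 0.0934 score units (SD over genes; adjusted p = 9.76e-15 by camera, and adjusted p = 0.524 with an estimated correlation). Among them rplS scored 7.51 ± 0.0561 at 0 h and 7.93 ± 0.0846 at 2 h (SD, n = 2), and rpmJ scored 8.40 ± 0.0381 and 8.75 ± 0.0517. The HrcA list had 4 of 6 genes higher on both arrays and none lower, with a mean difference of 0.111 (adjusted p = 0.000409, and adjusted p = 0.524 with an estimated correlation). Its chaperonin gene groES scored 6.36 ± 0.0382 at 0 h and 6.91 ± 0.175 at 2 h, while groEL differed by 0.0748, dnaK by 0.0155 and grpE by 0.0101. The 3 cold shock genes cspB, cspC and cspD, which encode RNA-binding proteins, were all higher, by 0.376, 0.0120 and 0.532 (list adjusted p = 0.000765, and adjusted p = 0.436 with an estimated correlation). In the ATP synthase operon 8 of 9 genes were higher, with a mean difference of 0.0198 that was 0.00988 without 2 h replicate 1 and 0.0297 without 2 h replicate 2 (adjusted p = 0.000382, and adjusted p = 0.584 with an estimated correlation). The ribosomal protein, HrcA, cold shock and ATP synthase directions were the same under every scaling tried.

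Of 43 flagella and chemotaxis genes, 34 were lower on both 2 h arrays than on both 0 h arrays and 0 were higher, with a mean difference of -0.0405 (adjusted p = 9.77e-13, and adjusted p = 0.524 with an estimated correlation). The flagellin gene hag scored 8.39 ± 0.202 at 0 h and 7.09 ± 0.391 at 2 h (SD, n = 2). The hook gene flgE differed by -0.0589, and the hook-associated gene flgL by -0.0566. These were the next widest of the 34, so hag weighs far more in the mean of -0.0405 than any other of them. In the SigB regulon 17 of 26 genes were lower and 1 higher, with a mean difference of -0.0448 (adjusted p = 3.37e-05, and adjusted p = 0.524 with an estimated correlation). Its stress protein gene gsiB scored 8.36 ± 0.0105 and 8.01 ± 0.196, while yflT differed by -0.349, ctc by -0.0830 and sigB itself by -0.0320. In the respiratory chain 11 of 15 genes were lower and 1 higher (adjusted p = 3.37e-05, and adjusted p = 0.524 with an estimated correlation). The cytochrome c oxidase genes ctaF and ctaE differed by -0.0306 and -0.0179, and the menaquinol:cytochrome c reductase gene qcrC by -0.0193. In branched-chain amino acid synthesis 7 of 8 genes were lower (adjusted p = 3.24e-07, and adjusted p = 0.436 with an estimated correlation), with leuC at -0.0138, ilvC at -0.00475 and ilvD at -0.00289. These flagella, SigB, respiratory and branched-chain directions at 2 h were the same under every scaling tried. These 4 lists and the ribosomal protein, HrcA, cold shock and ATP synthase lists passed camera without any 1 of the 6 arrays and in 10 other settings, those with an estimated correlation and fry aside.

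A further 8 lists passed camera at 2 h, less firmly. Peptidoglycan synthesis was higher for 12 of 15 genes, with murG at 0.0165 (adjusted p = 0.000234, 0.0551 without 2 h replicate 1 and 0.0593 after quantile normalization). Translation factors were higher for 5 of 10, with the initiation factor genes infA at 0.296 and infC at 0.178 (adjusted p = 0.00422, 0.0556 without 0 h replicate 2, 0.389 without 2 h replicate 1 and 0.501 after quantile normalization). RNA polymerase and elongation genes were higher for 5 of 8, with rpoA at 0.0979 (adjusted p = 0.00422, then 0.0610 and 0.273 without those arrays). The CtsR list was higher for 3 of 4 genes (adjusted p = 0.00840, and 0.0639 on ranks). It did not pass without either of those arrays. Its gene clpE scored 6.60 ± 0.0498 at 0 h and 7.27 ± 0.0242 at 2 h. Antibiotic synthesis was lower for 6 of 9 genes (adjusted p = 0.00129, and 0.0694 without 0 h replicate 1), with the surfactin synthetase genes srfAA, srfAB and srfAC at -0.0678, -0.0612 and -0.0561. The SigW envelope stress list was lower for 12 of 18 genes, by a mean of -0.00043 (adjusted p = 0.000234). After quantile normalization that mean was 0.00128 and the list no longer passed (adjusted p = 0.902). Extracellular proteases were lower for 5 of 8 genes (adjusted p = 0.00422, and 0.152 after quantile normalization or median centring). Osmoprotectant uptake tested as lower (adjusted p = 0.00810, and 0.0628 without 2 h replicate 2), with 7 genes lower, 5 higher and a mean of 4.07e-05 of the opposite sign. After quantile normalization that mean was 0.00126 (adjusted p = 0.717), and the adjusted p was 0.803 after median centring and 0.282 after centring on genes outside the translation lists, 0.0686 with the replicate block and 0.0639 on ranks. The mean was -9.89e-06 without 2 h replicate 2, -4.11e-05 without 0 h replicate 1, 0.000122 without 0 h replicate 2 and 9.12e-05 without 2 h replicate 1. With an estimated correlation none of the 40 lists passed at 2 h, and of these 8 the SigW, protease and osmoprotectant lists had an adjusted p = 0.436 with an estimated correlation. By that test RNA polymerase, CtsR and antibiotic synthesis had 0.524, peptidoglycan synthesis 0.584 and translation factors 0.616.

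Several genes outside the called lists also had wide differences. The oxidative stress list had a mean difference of -0.353 but did not pass (adjusted p = 0.108, and 0.0173 without either 4 h array), with 4 of 7 genes lower on both 2 h arrays. Its catalase gene katA scored 6.50 ± 0.104 at 0 h and 5.80 ± 0.119 at 2 h, and the alkyl hydroperoxide reductase genes ahpC and ahpF differed by -0.704 and -0.536. The DNA-binding protein gene mrgA differed by -0.513. The gene yneF, of no function named here, scored 7.46 ± 0.0367 at 0 h and 9.09 ± 0.107 at 2 h, a difference of 1.63 ± 0.156 (SE), and had the highest range over the 6 arrays, 1.74. The response regulator phosphatase gene rapA scored 7.55 ± 0.113 and 7.14 ± 0.0976, and ybyB scored 6.85 ± 0.156 and 6.12 ± 0.123.

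Gene by gene, limma called 2 higher at 2 h than at 0 h and 0 lower. They were ybaR, higher by 0.0590 ± 0.00124 (SE; adjusted p = 0.0156), and the feature BG11377/yqgI_at, unnamed here, higher by 0.244 ± 0.00388 (adjusted p = 0.0119). With an unadjusted p, 158 were higher and 219 lower, 377 in all against 240.3 expected by chance. After median centring the calls were 4 higher and 1 lower. Groups did not overlap for 888 higher (18.5%) and 1021 lower (21.2%), against 16.67% by chance for each. The other 9 named genes of smallest p differed as follows: clpE by 0.671, araB by 0.00544, araD by 0.00328, appB by -0.0210, ysdB by -0.00332, rapH by -0.00134, yceG by -0.000999, aspS by -0.000514 and aprE by -0.000246. Adjusted over the list alone, 21 list members passed in this comparison and 0 over all genes; they included 7 of 8 branched-chain genes, 5 osmoprotectant genes, 3 of 3 cold shock genes and 2 respiratory genes. Leaving out any 1 array gave 0 calls, and the other ways to part these 4 arrays into pairs gave 4 and 12 called lists against 16.

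**Figure D2:**
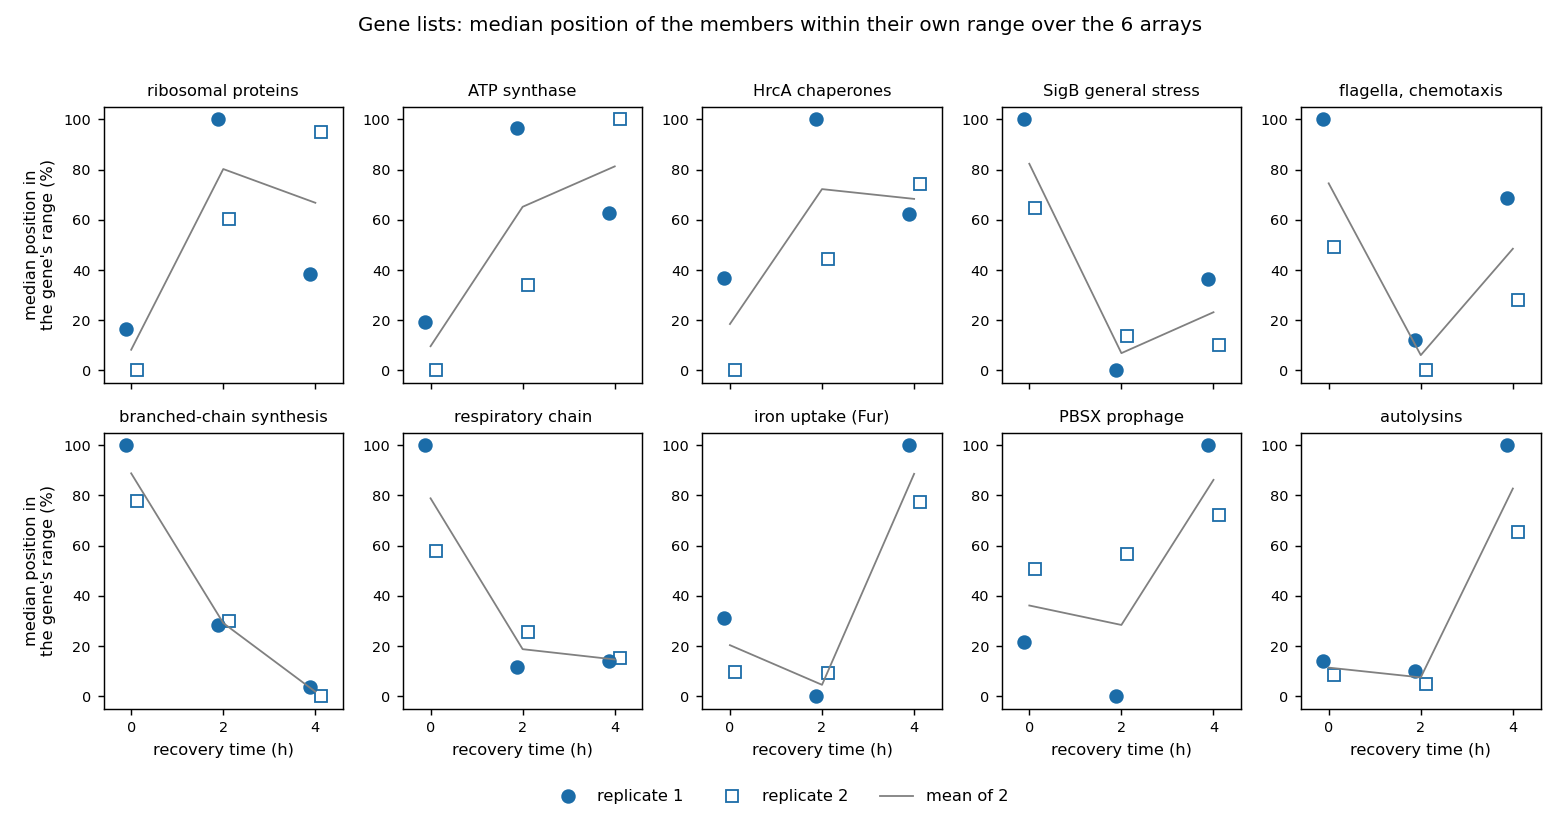
Median position of a list's genes within their own range over the 6 arrays (vertical axis, percent) against recovery time (horizontal axis, h), for 10 lists, with each replicate as a point and the mean as a line. Ribosomal protein genes lie at 0 and 16.5% at 0 h and at 60.5 and 100% at 2 h, and iron uptake genes lie at 77.2 and 100% at 4 h.

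At 4 h, when cells were growing again, iron uptake genes were higher than during growth arrest, as were genes of the autolysin and glycolysis lists. The iron list holds genes repressed by Fur, the iron-sensing repressor, among them genes for the siderophore bacillibactin, its uptake and flavodoxins. Autolysins cut peptidoglycan as the wall grows and as daughter cells part. Flagella genes and genes of the defective prophage PBSX were also higher, less firmly. As at 2 h, no list call held once the correlation between genes was estimated rather than preset. The comparison of 4 h with 2 h asks what distinguished re-growing from arrested cells.

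All 13 iron uptake genes measured were higher on both 4 h arrays than on both 2 h arrays, with a mean difference of 0.0446 ± 0.0980 (SD over genes; adjusted p = 3.96e-13, and adjusted p = 0.462 with an estimated correlation). fry also called this list, with an adjusted p of 0.0334, and the direction was the same under every scaling tried. The siderophore-binding protein gene feuA scored 6.10 ± 0.0187 at 2 h and 6.46 ± 0.121 at 4 h (SD, n = 2), and the bacillibactin synthesis gene dhbC differed by 0.0520. The gene ykuO, which lies in an operon with flavodoxin genes, was higher by 0.0527 ± 0.00117 (SE; adjusted p = 0.0135 by limma). Adjusted over the list alone, 10 of the 13 passed, and 1, ykuO, over all genes. All 5 genes of the autolysin list were higher, with lytE at 0.00863, lytD at 0.00602 and lytA at 0.00525 (adjusted p = 0.000170, and adjusted p = 0.562 with an estimated correlation). Not every gene of that list need encode an enzyme that cuts peptidoglycan. Of 5 glycolysis genes 4 were higher, with the aldolase gene fbaA at 7.13 ± 0.0504 and 7.33 ± 0.0124, pgi at a difference of 0.0574 and pgk at 0.0197 (adjusted p = 0.000210, and adjusted p = 0.562 with an estimated correlation). Autolysin and glycolysis directions were the same under every scaling tried.

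In the prophage PBSX, 19 of 27 genes were higher at 4 h and 0 lower, with xkdM at 0.0177 and xkdK at 0.00979 (adjusted p = 2.25e-08, and adjusted p = 0.562 with an estimated correlation). PBSX no longer passed after quantile normalization (adjusted p = 0.119), median centring (0.167) or centring on genes outside the translation lists (0.168). Of 43 flagella genes, 21 were higher and 0 lower (adjusted p = 3.97e-05, adjusted p = 0.748 with an estimated correlation, and 0.162 after quantile normalization). The flagellin gene hag scored 8.35 and 7.65 on the 4 h arrays, against 7.09 ± 0.391 at 2 h. The SigW list was higher for 13 of 18 genes, by a mean of 0.000384 (adjusted p = 4.83e-05, and adjusted p = 0.462 with an estimated correlation). It did not pass after quantile normalization, where the mean was -0.00513 (adjusted p = 0.154), after median centring (0.868) or after centring on genes outside the translation lists (0.618). Aminoacyl-tRNA synthetases were higher for 9 of 23 genes, with asnS scoring 7.05 and 7.06 (adjusted p = 0.000623, adjusted p = 0.562 with an estimated correlation, 0.0678 without 2 h replicate 2 and 0.129 without 4 h replicate 2). After quantile normalization that list had a mean of -0.00572 and an adjusted p of 0.119. Cell division genes were higher for 4 of 8 (adjusted p = 0.0180, adjusted p = 0.562 with an estimated correlation, 0.402 without 2 h replicate 2 and 0.129 without 4 h replicate 2), with a mean of -0.00763 and an adjusted p of 0.828 after quantile normalization.

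The oxidative stress list tested as higher with a mean of 0.137 (adjusted p = 0.0234, 0.112 without 2 h replicate 2), and its mean was -0.0174 without 4 h replicate 1 (adjusted p = 0.545), 0.291 without 4 h replicate 2 and 0.0891 without 2 h replicate 1. Its superoxide dismutase gene sodA scored 7.16 ± 0.0523 at 2 h and 7.30 ± 0.0375 at 4 h. The TCA cycle list was higher for 5 of 10 genes, with the succinyl-CoA synthetase gene sucC at 6.90 ± 0.0229 and 7.08 ± 0.0643 (adjusted p = 0.0286, 0.306 without 2 h replicate 2, 0.0542 without 4 h replicate 1 and 0.119 after quantile normalization). Fatty acid synthesis tested as higher, with the acyl carrier protein gene acpA, the 1 of 7 genes higher on both arrays, at 7.26 ± 0.386 and 7.71 ± 0.0294 (adjusted p = 0.0376, 0.599 without 2 h replicate 2, 0.472 without 4 h replicate 2, 0.0523 without either 0 h array, 0.187 after quantile normalization, 0.0598 with the replicate block and 0.0572 without the dimmest 25% of genes). Lower at 4 h were osmoprotectant uptake (9 of 15 genes; adjusted p = 0.0101, and 0.0678 without 2 h replicate 2), branched-chain synthesis (6 of 8; adjusted p = 0.0234, 0.0897 without 2 h replicate 2 and 0.129 without 4 h replicate 2) and histidine synthesis (6 of 7; adjusted p = 0.0392, 0.388 without 2 h replicate 2, 0.0984 without 4 h replicate 1 and 0.129 without 4 h replicate 2). After quantile normalization, median centring and centring on genes outside the translation lists these had an adjusted p of 0.187, 0.285 and 0.106 for osmoprotectant uptake, 0.681, 0.211 and 0.540 for branched-chain and 0.304, 0.242 and 0.231 for histidine synthesis, and without the dimmest 25% of genes the latter pair had 0.106 and 0.138. The osmoprotectant mean of -6.09e-05 was 7.15e-05 without 4 h replicate 1 and -0.000193 without 4 h replicate 2. It was -0.000111 without 2 h replicate 1 and -1.03e-05 without 2 h replicate 2. With an estimated correlation none of the lists passed at 4 h against 2 h. The osmoprotectant, branched-chain and histidine lists had an adjusted p = 0.562 with an estimated correlation. By that test the TCA cycle had 0.572, oxidative stress 0.620 and fatty acid synthesis 0.753. Ribosomal protein genes did not pass (mean difference -0.0192, adjusted p = 0.463): their mean was 0.0235 without 4 h replicate 1 (adjusted p = 0.00388), 0.00826 without 2 h replicate 1 (0.0441), -0.0466 without 2 h replicate 2 (0.0101) and -0.0618 without 4 h replicate 2 (2.38e-07). After median centring the test pointed to higher while the mean was -0.0203.

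Among genes with widely differing scores, the cold shock gene cspD scored 7.44 ± 0.177 at 2 h and 7.85 ± 0.113 at 4 h, and the ribose transporter gene rbsA scored 6.47 ± 0.172 and 6.83 ± 0.0368. The gene yolA scored 5.63 ± 0.0712 and 6.00 ± 0.0979. The CtsR list gene clpE scored 6.85 ± 0.0869 at 4 h, between its scores at 0 h and 2 h. The gene mtlD scored 6.75 ± 0.0290 at 0 h, 6.92 ± 0.00526 at 2 h and 6.76 ± 0.00536 at 4 h. By limma, 1 gene was higher, ykuO, and 2 were lower, ybaR by -0.0546 (adjusted p = 0.0135) and BG11377/yqgI_at by -0.181 (adjusted p = 0.0135). After quantile normalization the calls were 3 higher and 4 lower, after median centring 5 and 5. With an unadjusted p, 262 were higher and 209 lower. Groups did not overlap for 781 higher (16.25%) and 1193 lower (24.8%), against 16.67% by chance for each. The other 8 named genes of smallest p were yomZ, yomU, yonD, yonB, glpF, araD, araB and aprE, at differences of 0.00165, 0.00338, 0.0119, 0.0225, 0.0417, -0.00398, -0.00581 and -0.000145. Adjusted over the list alone, 23 list members passed in this comparison. The other ways to part these 4 arrays into pairs gave 1 and 15 called lists against 14, and leaving out any 1 array gave 0 called genes.

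**Figure D3:**
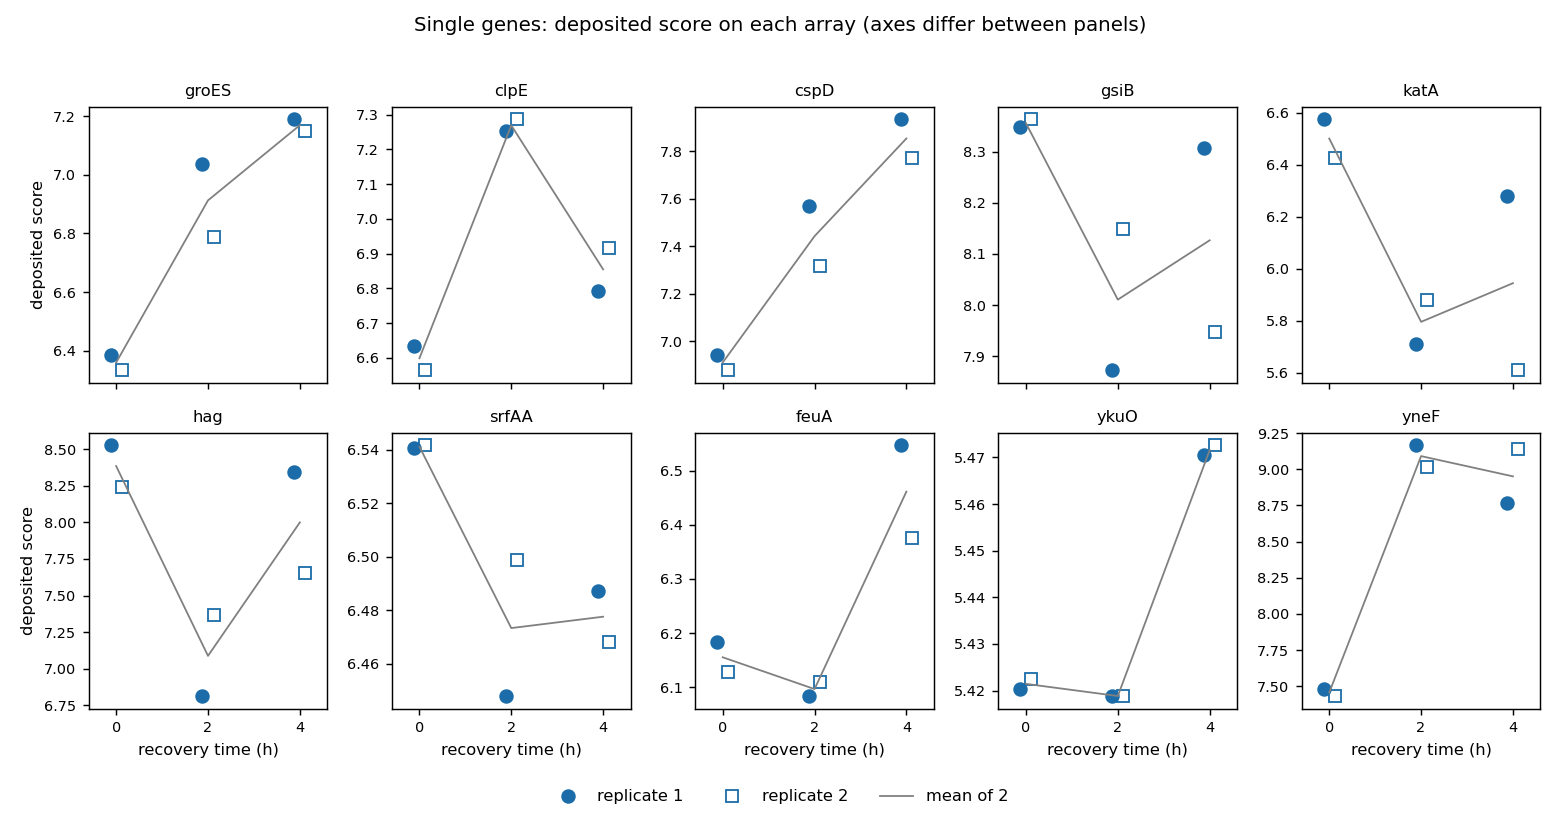
Deposited score (vertical axis, score units, a different axis in each panel) of 10 genes against recovery time (horizontal axis, h), with each replicate as a point and the mean as a line. The flagellin gene hag scores 8.35 and 7.65 on the 4 h arrays, and groES scores 6.36 at 0 h, 6.91 at 2 h and 7.17 at 4 h on average.

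Between 0 h and 4 h, genes of the ribosomal protein, translation factor, cold shock, ATP synthase, glycolysis, autolysin and iron uptake lists were higher in re-growing cells. Chaperone genes of the HrcA list, groES above all in score, were higher too. Branched-chain amino acid synthesis, antibiotic synthesis and respiratory chain genes were lower. Here too the list calls depend on the preset correlation, and none was left with an estimated one. The comparison of 4 h with 0 h asks how far recovering cells had moved from the state directly after pressure.

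Of 48 ribosomal protein genes, 43 were higher on both 4 h arrays than on both 0 h arrays and 1 was lower, with a mean difference of 0.0876 ± 0.0733 that was 0.0450 without 4 h replicate 2 (SD over genes; adjusted p = 2.71e-10, and adjusted p = 0.464 with an estimated correlation). The iron list was higher for 12 of 13 genes (adjusted p = 1.04e-09, and adjusted p = 0.464 with an estimated correlation), and fry called it with an adjusted p of 0.0260. The cold shock genes were higher for 3 of 3, with cspD at 0.943 and cspB at 0.472 (adjusted p = 0.000813, adjusted p = 0.464 with an estimated correlation, and 0.0290 by fry). Translation factors were higher for 7 of 10, with infA at 7.64 ± 0.00941 and 7.84 ± 0.146 (adjusted p = 0.000786, and adjusted p = 0.464 with an estimated correlation). ATP synthase was higher for 7 of 9 genes and glycolysis for 5 of 5 (adjusted p = 0.000382 for each, and adjusted p = 0.464 with an estimated correlation for each). Autolysins were higher for 3 of 5 genes, with none lower (adjusted p = 0.000845, and adjusted p = 0.464 with an estimated correlation). These 7 lists passed camera without any 1 array and in the 10 other settings, those with an estimated correlation and fry aside, and kept their direction under every scaling tried. Autolysins were tested in 9 of those settings, having too few members without the dimmest 25% of genes. The gene acpA differed by 0.671, groES by 0.810 and yneF by 1.49.

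Of the lists in the rest of this comparison, flagella and arginine synthesis had an adjusted p = 0.679 with an estimated correlation, fatty acid synthesis 0.504, protein secretion 0.5004, HrcA 0.487 and each of the others 0.464. Branched-chain synthesis was lower for 7 of 8 genes (adjusted p = 2.46e-06, and 0.0260 by fry), and after centring on genes outside the translation lists its adjusted p was 0.0502. Antibiotic synthesis was lower for 9 of 9 genes (adjusted p = 0.000573, 0.0695 after quantile normalization and 0.261 after centring on genes outside the translation lists). The respiratory chain was lower for 11 of 15 genes (adjusted p = 0.00182, and 0.629 after centring on genes outside the translation lists). The SigB list was lower for 18 of 26 genes and the flagella list for 19 of 43, but the test of each pointed to higher after centring on genes outside the translation lists (adjusted p = 0.00340 and 0.00575, and 0.726 and 0.342 after that centring). Their adjusted p was 0.163 and 0.308 after median centring, and that of SigB 0.0827 after quantile normalization. The flagella mean of -0.0136 was -0.00662 without 0 h replicate 1 (adjusted p = 0.202) and -0.00243 without 4 h replicate 2 (0.412). The arginine synthesis test also pointed to higher after that centring (4 of 9 genes lower, adjusted p = 0.0457, and 0.549 after it, 0.392 after median centring and 0.728 after quantile normalization), and it did not pass without any 1 of the arrays except 0 h replicate 1, from 0.103 without 2 h replicate 1 to 0.831 without 0 h replicate 2, where its mean of -0.0693 became 0.00535. The osmoprotectant uptake list was also called by fry. Osmoprotectant uptake was lower for 10 of 15 genes (adjusted p = 0.000845, and 0.294, 0.296 and 0.128 after quantile normalization, median centring and centring on genes outside the translation lists). Histidine synthesis was lower for 7 of 7 genes (adjusted p = 0.00793, then 0.247, 0.214 and 0.230). The osmoprotectant mean of -2.02e-05 was -0.000102 without 0 h replicate 1 and 6.15e-05 without 0 h replicate 2. It was 0.000112 without 4 h replicate 1 and -0.000153 without 4 h replicate 2. The competence test pointed to lower, with 12 of 16 genes lower but a mean of 4.63e-06, which was -0.000154 without 0 h replicate 1, 0.000163 without 0 h replicate 2, 8.01e-05 without 4 h replicate 1 and -7.08e-05 without 4 h replicate 2 (adjusted p = 0.0381, 0.345 without 0 h replicate 2 and 0.205 without 4 h replicate 1, 0.781, 0.280 and 0.144 after those scalings, 0.0735 with the replicate block and 0.211 without the dimmest 25% of genes).

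Peptidoglycan synthesis was higher for 13 of 15 genes (adjusted p = 0.000382, 0.0514 without 4 h replicate 2 and 0.0502 after quantile normalization). PBSX was higher for 20 of 27 (adjusted p = 9.34e-06, and 0.122, 0.405 and 0.339 after quantile normalization, median centring and centring on genes outside the translation lists). The HrcA list was higher for 4 of 6 (adjusted p = 0.0184, 0.161 without 0 h replicate 2 and 0.0556 without 4 h replicate 2). Aminoacyl-tRNA synthetases were higher for 10 of 23 genes (adjusted p = 0.000845), with a mean of -0.00345 and an adjusted p of 0.405 after quantile normalization. Cell division was higher for 5 of 8 genes (adjusted p = 0.00358), with a mean of -0.00165 and an adjusted p of 0.751 after that normalization. RNA polymerase (adjusted p = 0.0169, 0.0647 without 0 h replicate 2 and 0.184 without 4 h replicate 2), fatty acid synthesis (0.0173, then 0.0647 and 0.332) and protein secretion (0.0253, then 0.247 and 0.103) were higher, with 0.328, 0.0827 and 0.107 after quantile normalization. Secretion stress tested as higher (0.0370, 0.233 without 0 h replicate 2 and 0.293 without 4 h replicate 1), with a mean of -0.00637 and an adjusted p of 0.847 after quantile normalization, and 0.0541 without the dimmest 25% of genes. The CtsR list tested as higher (0.0430, 0.218 without 0 h replicate 2, 0.0502 without 4 h replicate 1 and 0.104 without 4 h replicate 2, and 0.0649 with the replicate block, 0.0569 on ranks and 0.0606 without the dimmest 25% of genes). Lower were anaerobic genes (0.0186, 0.0579 without 0 h replicate 1 and 0.0885 without 4 h replicate 1), extracellular proteases (0.0344, 0.123 without 0 h replicate 1 and 0.103 without 4 h replicate 2) and SigF-dependent sporulation genes (0.0370, from 0.0516 without 0 h replicate 1 to 0.0965 without 4 h replicate 1, and also 0.0739 without 0 h replicate 2 and 0.0661 without 4 h replicate 2). After quantile normalization, median centring and centring on genes outside the translation lists these had 0.201, 0.214 and 0.263 for anaerobic genes, 0.348, 0.568 and 0.588 for proteases and 0.751, 0.280 and 0.227 for SigF-dependent genes. Without the dimmest 25% of genes they had 0.0582, 0.0505 and 0.171, and proteases had 0.0794 with the replicate block and 0.0952 on ranks. The mean of the SigF-dependent list was only -0.000255 score units. As sigF is disrupted in the strain of all 6 arrays, a call of that list in any comparison need not reflect SigF activity. Extracellular proteases were also called by fry at 4 h against 0 h. The protease mean of -0.00145 changed sign to 0.00140 without 0 h replicate 1 and 0.000869 without 4 h replicate 2. It was -0.00431 without 0 h replicate 2 and -0.00378 without 4 h replicate 1.

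By limma, ykuO was higher at 4 h than at 0 h by 0.0501 ± 0.00117 (SE; adjusted p = 0.0439) and the subtilisin gene aprE lower by -0.000391 ± 1.12e-05 (adjusted p = 0.0441). With an unadjusted p, 318 were higher and 352 lower, and without any 1 array the calls were 0. After quantile normalization the calls were 6 higher and 4 lower. Centring on genes outside the translation lists gave 140 higher and 3069 lower here, and 122 higher and 2998 lower at 4 h against 2 h. Groups did not overlap for 1039 higher (21.6%) and 1646 lower (34.25%), against 16.67% by chance for each. The other 8 named genes of smallest p were yomZ, yonD, yomU, rapH, ysdB, ipi, appB and yoaA, at differences of 0.00183, 0.0129, 0.00346, -0.00227, -0.00216, -0.00150, -0.0271 and -0.000216. Adjusted over the list alone, 41 list members passed. The other ways to part these 4 arrays into pairs gave 7 and 9 called lists against 29.

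Over the time course, ribosomal protein genes were higher at both later times than directly after pressure, while flagella genes were lower at 2 h and in part higher again at 4 h. Of the 48 ribosomal protein genes, 39 were higher than at 0 h on both arrays of both later times. Of the 43 flagella genes, 19 were lower at 2 h and higher again at 4 h, and 16 were lower than at 0 h at both later times, where a gene can be in both counts. At both later times 14 SigB genes, 11 respiratory chain genes and 7 branched-chain genes were lower. Centring on genes outside the translation lists, however, turned the SigB and flagella tests at 4 h against 0 h to higher. It also ended the respiratory chain and branched-chain calls there (camera adjusted p = 0.629 and 0.0502). Among all genes, 448 of the 888 higher at 2 h (50.5%) were also higher at 4 h than at 0 h, against 42.7% in simulated unchanged groups. Of the 1021 lower at 2 h, 680 (66.6%) were also lower at 4 h, against 38.6% simulated, and 234 (22.9%) were higher at 4 h than at 2 h, against 39.9% simulated. Both later times are compared with the same 0 h arrays, so the excess is not independent of those arrays.

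Of 13 genes fixed for reporting whatever their value, 11 had a named feature. The elongation factor gene tufA scored 9.40 at 0 h and 2 h and 9.41 at 4 h. Of the others, infB scored 6.68, 6.69 and 6.68, and the CtsR list gene clpC scored 7.48 at all 3 times. The division gene ftsZ scored 7.08 at all 3 times, sigF, the disrupted gene, 6.88 and trpC 5.20. With no array of an intact strain, the sigF score tells nothing about the insertion. The chaperone genes groEL and dnaK scored 7.74 and 6.54 at 0 h and 7.85 and 6.55 at 4 h. The sigB gene scored 6.23 at 0 h and 6.20 at both later times. On the 4 h arrays katA scored 6.28 and 5.61. The 8 lists that passed in none of the comparisons were the SOS regulon, early sporulation, purine, pyrimidine and tryptophan synthesis, arginine degradation, sulfur and methionine genes and DNA replication, with adjusted p from 0.0805 to 0.950. Among these, leaving out an array gave a call for early sporulation at 4 h against 2 h (0.0198 without 4 h replicate 2) and for purine synthesis (0.0250 at 2 h against 0 h and 0.0348 at 4 h against 2 h, each without 2 h replicate 2). DNA replication passed at 2 h against 0 h without 0 h replicate 1 (0.00725) or 2 h replicate 2 (0.0365), and at 4 h against 2 h without the latter (0.0348). Arginine degradation passed at 2 h against 0 h without 0 h replicate 2 (0.000241), at 4 h against 2 h without either 0 h array (0.00613), and at 4 h against 0 h as higher without 0 h replicate 1 (0.0180) and as lower without 0 h replicate 2 (0.0355). Other settings gave calls too. Arginine degradation passed after quantile normalization, median centring and centring on genes outside the translation lists at 2 h against 0 h (0.0495, 0.0147 and 0.0229) and at 4 h against 2 h (0.00737, 0.000107 and 0.000136), the latter also on ranks (0.0492), and at 4 h against 0 h with the last centring (0.0366). With the replicate block tryptophan synthesis passed at 2 h against 0 h (0.0485) and 4 h against 2 h (0.0468). After quantile normalization DNA replication passed at 4 h against 2 h (0.00692) and 4 h against 0 h (0.0330).

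Other lists that did not pass in a comparison passed there when an array was left out. At 2 h against 0 h these were competence (adjusted p = 0.0332 without 0 h replicate 1 and 0.0243 without 2 h replicate 2), protein secretion (0.0215 and 0.00256 without those arrays) and arginine synthesis (2.70e-05 without 0 h replicate 1). Glycolysis (0.0324) and histidine synthesis (0.0349) passed without 2 h replicate 2, and iron uptake without either 4 h array (0.0402). PBSX tested as higher without 2 h replicate 1 (0.00308) and as lower without 2 h replicate 2 (0.00167). At 4 h against 2 h, translation factors (0.00648 and 0.000880), antibiotic synthesis (0.0158 and 0.0401), ATP synthase (0.00378 and 0.0498) and peptidoglycan synthesis (0.0372 and 0.00575) passed without 2 h replicate 1 and without 4 h replicate 1. Secretion stress (0.0217) and protein secretion (0.00384) passed without 2 h replicate 1, and the cold shock list without 4 h replicate 1 (0.0346). SigF-dependent sporulation genes passed without either 0 h array (0.0373) or 2 h replicate 1 (0.0234), with the replicate block (0.0424) and on ranks (0.0206).

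Scaling gave further calls of lists that did not pass in a comparison. After median centring and centring on genes outside the translation lists these were oxidative stress (adjusted p = 0.00225 and 0.0165) and iron uptake (0.0310 and 0.0229) at 2 h against 0 h, both lower. At 4 h against 2 h they were SigB (0.000572 and 6.54e-05, and 0.0497 on ranks), cold shock (0.000679 and 0.00126), ATP synthase (0.00110 and 0.000126) and translation factors (0.00142 and 0.000343). All of these tested as higher, translation factors with means of -0.00365 and -0.00346. At 4 h against 0 h it was the TCA cycle (0.00899 and 0.00380). Median centring alone gave protein secretion at 2 h against 0 h (0.00697), and quantile normalization aminoacyl-tRNA synthetases (0.0495). Trend and robust settings gave competence there (0.0315). With centring on genes outside the translation lists, RNA polymerase (0.0342, mean -0.00728), HrcA (0.0146, mean 0.0465), secretion stress (0.0266, mean 0.000264) and peptidoglycan synthesis (0.0119, mean -0.000959) passed at 4 h against 2 h. So did oxidative stress at 4 h against 0 h (0.0282, mean -0.217). The direction of such a test, made against the other genes, need not be that of the mean. At 4 h against 2 h median centring moved the median difference by -0.00118, more than the whole range of 3089 genes. Centring on genes outside the translation lists moved it by -0.000996, more than the range of 2994. At 4 h against 0 h these numbers were 3116 and 2974. A list of wider-ranging genes can then pass as higher because other genes were moved down. Such calls at 4 h need not reflect a change in the list.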

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

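Of the alternatives, the crossed replicate block, the names in identifiers and features not averaged were chosen after seeing the data.

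Of 59 list calls in the 3 comparisons, 59 were kept with the trend and robust settings, the floor and the names in identifiers, 57 with only the 2 times compared, 55 on ranks, 54 with the replicate block, 42 with median centring, 40 with centring on genes outside the translation lists and 27 with quantile normalization. Without the dimmest 25% of genes 48 of 57 were kept, and without 1 array 44 to 54. With an estimated correlation 0 were kept, with fry 6. Calls were also gained: 15 with centring on genes outside the translation lists, 10 with median centring, 5 with quantile normalization, 4 with only the 2 times compared, 3 each with the replicate block and on ranks, 1 with trend and robust settings and 3 to 10 without 1 array. Calls kept without any 1 array and in each of the 10 other settings in which the list could be tested (9 for autolysins) numbered 8 of 16, 3 of 14 and 7 of 29. The cause of the losses and gains was not tested. At 4 h, however, both centrings moved most genes down by more than their range, which alone can alter a test made against other genes. Other splits of the same 4 arrays called 4 and 12 lists against 16, 1 and 15 against 14, and 7 and 9 against 29. With 3 splits no share under 0.05 can be had, and why 12 and 15 were called was not tested.

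For each gene count above 0, the replicate block, only the 2 times compared, the minimum difference of 1 score unit, the stricter adjusted p and each left-out array (0 to 0) gave 0 genes. The minimum difference and the stricter adjusted p of 0.01 could give nothing else. The widest called difference was 0.244, and the lowest adjusted p by limma was 0.0119. The deviations of replicates correlated at 0.251, -0.505 and 0.177 between times, and at 0.412, -0.057 and 0.171 as shares of each gene's range, so replicate numbers were not taken to pair the samples. A crossed replicate block gave 0 higher and 1 lower at 4 h against 2 h. Median centring gave 4 higher and 1 lower at 2 h against 0 h, 5 and 5 at 4 h against 2 h, and 5 higher at 4 h against 0 h. Quantile normalization gave 3 and 4 at 4 h against 2 h, and 6 and 4 at 4 h against 0 h. Without the dimmest 25% of genes 2 were higher at 4 h against 2 h, and 0 higher and 0 lower at 4 h against 0 h. Trend and robust settings gave 4 higher at 4 h against 2 h. The floor, the names in identifiers and features not averaged left the gene counts as they were. Centring on genes outside the translation lists gave 122 higher and 2998 lower at 4 h against 2 h, and 140 and 3069 at 4 h against 0 h. That centring moves the median difference by -0.000996 and -0.000959, and 2806 and 2775 of these lower calls are of genes whose range over the 6 arrays is below that move, so the move makes most of them. Median centring moves it further (-0.00118 and -0.00124) with few calls, but its constants differ more between replicates (0.00144 and 0.000175 at 4 h, against 0.000820 and 0.000483), which adds to the spread within a time. No scaling moved the median by over 0.1, but only 180 of 4806 genes and unnamed features had a range that wide. That bound therefore says little.

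The ribosomal protein mean of 0.107 at 2 h had an adjusted p of 0.524 with an estimated correlation and 0.364 with fry, and the mean of 0.0876 at 4 h against 0 h had 0.464 and 0.299. At 4 h against 2 h it was -0.0272 after quantile normalization, -0.0203 after median centring and -0.0202 after centring on genes outside the translation lists, where the last pair tested as higher (adjusted p = 0.00539 and 6.23e-07), and -0.0618 to 0.0235 without 1 array. Quantile normalization turned SigW (0.00128) and osmoprotectant uptake (0.00126) at 2 h, aminoacyl-tRNA synthetases (-0.00572), SigW (-0.00513) and cell division (-0.00763) at 4 h against 2 h, and aminoacyl-tRNA synthetases (-0.00345) at 4 h against 0 h. Centring on genes outside the translation lists turned the tests of SigB (mean -0.0272), flagella (-0.0145) and arginine synthesis (-0.0703, but 0.00535 without 0 h replicate 2) at 4 h against 0 h, and moved yceG to -0.000901 at 4 h against 2 h and aspS and trpC to -0.000926 and -0.000959 at 4 h against 0 h. Without 1 array the PBSX mean at 2 h ran from -0.000754 to 0.000364 and arginine degradation at 4 h against 0 h from -0.0678 to 0.115. The cause was not tested. Scores of dim genes barely move, and signal over background is not known for a score, so small differences there are the least certain.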

Other observations

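The tests of scaling, of a score trend in the 4 h replicates, of a mislabelled array, of an array less far along and of a joint shift of the SP-beta genes were chosen after the results they measure were seen and took the place of earlier versions whose outcome was known; the others were chosen before. A pair of further tests, on the unequal spread of genes, was run and left out, and the spread itself is given with the methods.

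Some features of wide range have no symbol in the annotation table used here. BG11479/yydF_at scored 8.35 and 8.43 at 0 h, 7.79 and 7.71 at 2 h and 7.60 and 7.42 at 4 h. BG12311/ysbA_at scored 5.79 and 5.85 at 0 h, 5.72 and 5.83 at 2 h and 6.70 and 6.50 at 4 h. BG12901/yfiY_at scored 6.92 on both 4 h arrays and at most 6.50 before. Its identifier holds the name of a member of the iron uptake list, yfiY, which was not among the 13 measured there. BG10740/yvyD_at scored 7.84 and 7.74 at 0 h, 7.23 and 7.36 at 2 h, and 7.75 and 7.29 at 4 h. Of 606 intergenic features, 238 were lower on both 4 h arrays than on both 2 h arrays and 29 higher, against 24.8% lower and 16.25% higher among all; at 2 h against 0 h 98 were lower and 78 higher, and at 4 h against 0 h 260 and 50. Of 36 tRNA features 10 were higher and 2 lower at 2 h against 0 h, 1 higher and 19 lower at 4 h against 2 h, and 0 higher and 4 lower at 4 h against 0 h.

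Ribosomal protein genes were higher at 2 h than at 0 h. A trend with the score is argued against: the list's median difference lay above all of 10000 lists matched on mean score (percentile 100), whose highest median was 0.00576. Those lists drew genes singly and were not matched on range, while the ribosomal protein genes had an estimated correlation of 0.817. The percentile therefore speaks to the score alone and is no measure of chance for genes that move together. Scaling of whole arrays is argued against as the whole cause by quantile normalization alone. After it the mean difference of 0.107 was 0.101, the lowest over the 3 scalings tried. Its SE over genes of 0.0131 treats genes as independent. The camera adjusted p was 8.69e-09 with the preset correlation, the highest of the 3 scalings. That normalization, however, moved 47.6% of other genes by more than their range. The 2 centrings could not have removed the difference, as they moved the median difference by only -5.91e-05 and 3.68e-05. Of the 3 splits of the 4 arrays, 1, the real one, gave as low a camera p (-log10 p 15.6, highest other 3.10), which is too few splits for a share under 0.05. A change between growth-arrested and just-pressed cells stays open as the biological explanation, untested.

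The 4 h replicates lay apart in the flagella, oxidative stress and SigB lists, and not in these alone: 23 of 27 PBSX genes were higher on replicate 1, but 0 of 48 ribosomal protein, 0 of 15 peptidoglycan, 0 of 9 ATP synthase and 0 of 7 fatty acid genes. Nor was the gap particular to 4 h. On 0 h replicates 1 and 2 the median positions of members within their own range were 100 and 49.1% for flagella. They were 100 and 64.7% for SigB and 89.5 and 52.1% for oxidative stress. At 4 h they were, in that order of lists, 68.8 and 28.2%, 36.4 and 10%, and 96.5 and 23.9%. At 2 h they were 12.2 and 0%, 0 and 13.8%, and 10.7 and 21.8%. The gap at 0 h was not tested. For the 4 h gap a trend with the score is argued against: 65 of 76 genes were higher on 4 h replicate 1 than on 2, a mean z of 3.50 over the 3 lists. That z lay above the 3 most one-sided of 40 matched lists in all of 10000 draws (percentile 100, highest 3.16). The matched lists here and in the next test drew genes singly. Their percentiles speak to the score alone and are no measure of chance for genes that move together. That 4 h replicate 2 is a plain 2 h array is argued against: of iron uptake genes, the list with the lowest camera p without it, 92.3% (12 of 13) lay above both 2 h arrays on it by more than the gap between those, against at most 7 in matched lists (percentile 100). Other lists were mixed: over the lists called without it, flagella and oxidative stress aside, 48.1% of members (74 of 154) lay beyond both 2 h arrays in the called direction, and of 48 ribosomal protein genes, called lower without it, 20 lay above both and 1 below. It may have been less far along the change from 2 h to 4 h: 58.9% of members of the other called lists (86 of 146) lay between the 2 h mean and 4 h replicate 1, between the limits set for and against, so a less advanced culture stays open, as does a mixture, which was not tested.

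Genes of the SP-beta prophage region were among the smallest p at 4 h. The list of 152 genes by symbol prefix was added after that. Their median score was 5.311, against 5.203 at the 5th percentile of each array, so many of them were dim. At 4 h against 2 h, 78 of the 152 were higher on both arrays and 11 lower. The highest number among matched lists was 39 (percentile 100), which argues against a trend with the score alone. The 78 include the 4 genes that drew attention to the region, and the matched lists drew genes singly. As the list was drawn from these same data, the percentile is no measure of chance. Without the 4 genes that drew attention to the region, camera with an estimated correlation gave p = 0.0230, unadjusted. With all genes and adjusted over the lists it was 0.315. The mean difference of the 152 genes was 0.00498 score units but the median was 1.02e-05, so a few genes weigh most in the mean. The gene yolA scored 5.68 and 5.58 at 2 h and 6.07 and 5.93 at 4 h. For yolB the scores were 6.02 and 5.99, then 6.29 and 6.17. A small joint shift of part of the region stays open, and a shift of the whole region is not shown. Other causes of a joint shift, the deposited normalization among them, were not tested, so the shift is a hypothesis.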
